A study of Gallus gallus with 31 samples.

How the data were processed

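The samples were abdominal and cardiac fat of male chickens of 42 days, flash frozen, from which polyA RNA was sequenced with a stranded Illumina kit, per the labels' protocols. The authors used Bowtie, TopHat and Cufflinks, per the submitters' processing notes. Their versions, the genome build and the annotation are not given in the sources used here. The deposited values are FPKM, fragments scaled to transcript length and to the mapped fragments of the library, with 1 value per gene and library. The file headers do not name the unit, and FPKM was taken from the named tool and the range of the values. FPKM divides each library by its own total, so a gene that takes a large share of the fragments lowers the values of all others, and the model of each transcript enters its value.

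The part of the table analysed here held 567 lines of genes in order of Entrez number, of which 566 were complete. The last was incomplete and was left out, and genes beyond it were not analysed here. After 2 exact duplicate lines (EEF1A1 and HOXA3) were removed, 564 genes remained. Every column matched 1 library by its number, tissue and line, and 0 columns were unmatched. A value of 0.001 stood in 2279 cells, with 1 value below it. It is a floor and not a measured level. A total of 63 genes were listed at 0.001 in a library and at 5 FPKM or more in another of the same group, 54 of them among the tested genes, so such genes were described by single values where all libraries of a group were at the floor. Gene names are those of the table. Of 564 Entrez numbers, 562 were found in the table of assembly GRCg7b, 541 with the same symbol and 21 with another, among them SS2, CTGF, IGJ and ATP5A1. That table was used for names only, and no coordinates are given because the build of the deposited values is not given in the sources used here. Genes with close copies, such as RPL35 and ATP5A1, are uncertain where fragments were shared between copies.

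Depth could not be read from FPKM directly. Low values of a gene are multiples of what 1 fragment is worth in a library, and comparing these steps between libraries gave relative depths. With them, 83.1% of 1204 low values in 103 genes came within 0.05 fragments of a whole number, against 27.3% on average when depths were shuffled among libraries. In such a gene, 1 fragment stood for about 0.03 FPKM at median depth, so a value of 1 FPKM rested on about 33.3 fragments. The relative depths of Illinois cardiac library 1113 and Ross abdominal library 1196, 2.18 and 1.07, are the highest of their groups and may be wrong by a whole factor.

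Values were analysed as log2(FPKM + 1) in R 4.3.3 with limma 3.58.1 (statmod 1.5.0), in genes with at least 1 FPKM in at least 7 libraries. A fold change on this scale understates the change of low genes. The model held 4 group means and an additive trial term over all 31 libraries, which share 1 estimate of the spread, with a mean-variance trend and robust moderation. Contrasts were cardiac minus abdominal in each line and averaged, Ross minus Illinois in each depot, and the difference of the depot effects. The trial was tested in the 16 Ross libraries with depot as a term. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg, and genes with an adjusted p below 0.05 were called.

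The tests, samples, covariates, gene lists and the rule for named genes were fixed before the data were examined. That rule took, for each depot and line comparison, the 8 largest positive and 8 largest negative fold changes among called genes with a mean of at least 5 FPKM in the higher group. It added the 4 largest each way for the difference of depot effects, up to 4 called members of each described list, and PPARG and FABP4 always. The results of 1 gene that met this rule are not reported here. Other named genes were chosen after their values were seen, as were those of the trial comparison. Of 31 gene lists, 28 had a tested member and 6 had at least 5. Those 6 (extracellular matrix and fibroblasts, endothelium, anterior and cardiac developmental regulators, insulin and growth hormone axis, ribosomal proteins, clock genes) were tested with camera at a preset correlation of 0.01 and again with an estimated one, and with fry. The lists of the insulin and growth hormone axis, ribosomal proteins and clock genes passed camera at the preset correlation on the values as given in no comparison, the lowest adjusted p being 0.0519 for clock genes between the Ross depots. With other settings, the clock list was lower by fry between the Ross depots (adjusted p = 0.0117; camera adjusted p = 0.374 with an estimated correlation), and the ribosomal protein list passed camera after quantile normalization between the Illinois depots (adjusted p = 0.00904; adjusted p = 0.843 with an estimated correlation).

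The steps were tested on simulated data made from the real means and spreads with 100 genes changed. At a log2 change of 1, 74.4% of changed genes were recovered for the Ross depots, 70.0% for the Illinois depots, 64.4% for the line in abdominal fat, 67.4% for the line in cardiac fat and 46.5% for the difference of depot effects, each over 423 genes. False calls made up 3.75% to 4.13% of calls. The simulated noise was normal and independent between genes, with no trial effect and no values set to the floor. These rates therefore hold only where the model holds, and do not measure false calls in the real data. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

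Alternatives fixed in advance were pseudocounts of 0.1 and 5, other filters, quantile and upper quartile scaling, no trial term, single trials, only the libraries compared, limma without trend, array weights, a test against a log2 change of 0.5, an exact rank test and leaving out each library. Added after seeing the data were a block on the second number of the column headers, leaving aside the 4 cardiac libraries with CASQ2 above 10 FPKM, CASQ2 as a covariate, and leaving out the 54 genes that alternate between the floor and clear expression. A count-based test was not run because the values are FPKM.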

Results

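The data are gene expression values of fat tissue from male chickens of 42 days, all labelled as controls. A total of 31 RNA libraries came from 2 fat depots, the abdominal fat pad and the fat around the heart, here called cardiac, of birds from 2 lines. Ross is a commercial broiler line, and the labels name the other only as Illinois. The groups held 7 Illinois abdominal, 8 Illinois cardiac, 8 Ross abdominal and 8 Ross cardiac libraries. All Illinois libraries belonged to a trial named Fall 13, while each Ross group held 4 libraries of that trial and 4 of a trial named Fall 12. The labels do not say whether libraries of the 2 depots came from the same birds, so p-values measure the spread between these libraries.

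The part of the expression table analysed here held 564 genes, of which 423 passed the filter on low values and were tested. These genes are a stretch of the table in order of gene number and not a random sample of the genome, so counts of genes and shares of summed values describe that stretch only. FABP4, a fatty acid carrier of fat cells, made up 43.0% ± 3.71 (SD, n = 7) of the summed FPKM of these genes in Illinois abdominal fat. Its share was 24.1% ± 9.32 in Illinois cardiac, 32.0% ± 4.91 in Ross abdominal and 33.2% ± 11.04 in Ross cardiac fat (n = 8 each). CASQ2, a calcium-binding gene of heart muscle, stood above 10 FPKM in 4 cardiac libraries. It reached 36.3 and 27.5 FPKM in Illinois cardiac libraries 1107 and 1112, and 77.2 and 18.1 FPKM in Ross cardiac libraries 1208 and 1209. FABP4 held 16.7% of the summed FPKM in Illinois cardiac library 1107, 8.17% in 1112 and 14.0% in Ross cardiac library 1208, but 34.5% in Ross cardiac library 1209, above the mean of its group. The total depth of the libraries is unknown. The steps between low values gave a mean depth relative to the typical library of 1.42 ± 0.147 in Illinois abdominal, 1.21 ± 0.413 in Illinois cardiac, 0.689 ± 0.167 in Ross abdominal and 0.877 ± 0.118 in Ross cardiac libraries (SD).

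**Figure D1:**
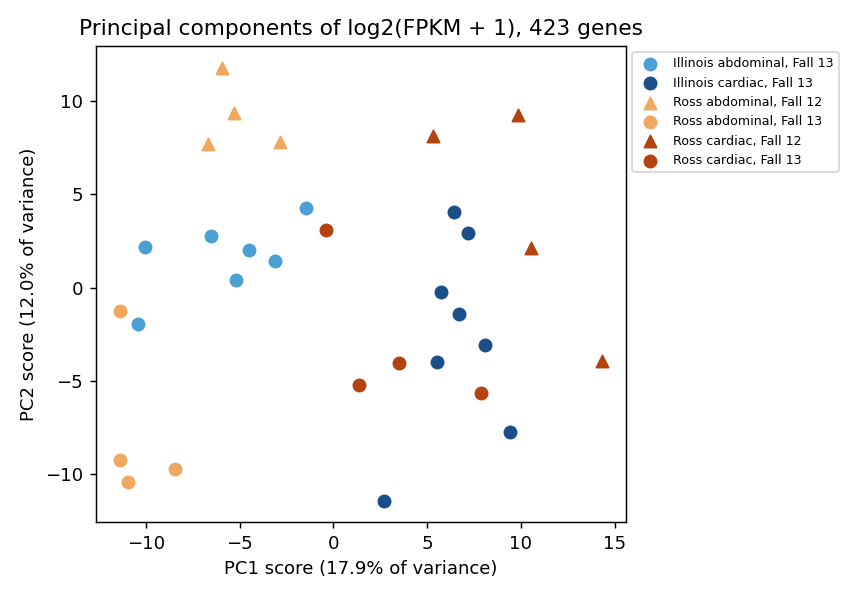
Scores of the 31 libraries on the first and second principal components of log2(FPKM + 1) over 423 genes, which held 17.9% and 12.0% of the variance. Each point is 1 library, colours mark the group, triangles mark Fall 12 and circles Fall 13. Cardiac libraries lie to the right of the abdominal libraries of the same line and trial.

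The first principal component set the depots apart within each line and trial. Its scores ran from -10.5 to -1.46 in Illinois abdominal and from 2.72 to 9.43 in Illinois cardiac libraries. The second separated the trials in Ross abdominal fat, with scores of 7.73 to 11.8 in Fall 12 and -10.4 to -1.26 in Fall 13. Correlations between libraries of 1 group lay between 0.776 and 0.950 across genes.

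The first comparison asked which genes differ between cardiac and abdominal fat in Ross birds. Of 5 tested T-box factors, genes that pattern the embryo, TBX20, TBX18 and TBX5 were higher in cardiac fat, TBX3 was lower (-0.90, adjusted p = 0.0207) and TBX2 was not called (-0.57, adjusted p = 0.146). TBX20 (Entrez 373943) averaged 0.238 ± 0.223 FPKM in abdominal and 17.8 ± 24.4 FPKM in cardiac fat (SD, n = 8 each), a log2 fold change of 3.41 (SE 0.33, adjusted p = 1.47e-08), and 8 of 8 cardiac libraries lay above the abdominal median. Library 1208 held 78.0 FPKM and the other 7 cardiac libraries 6.61 to 12.3, and without the 4 libraries with a muscle signal the log2 fold change was 2.96. TBX18 (Entrez 395104), a factor of the epicardium, rose from 3.05 ± 3.75 to 12.6 ± 2.38 FPKM (log2 fold change 2.30, adjusted p = 6.27e-05). In the other direction, PITX1 (Entrez 374201), a homeobox factor of the hindlimb, fell from 5.78 ± 4.93 to 0.0841 ± 0.0574 FPKM (log2 fold change -2.17, adjusted p = 8.31e-05), and NKX3-2, another homeobox factor, had a log2 fold change of -1.54 (adjusted p = 0.00549).

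Of the 9 tested developmental regulators of anterior and heart tissues, 3 were higher and 4 lower in Ross cardiac fat, and the same numbers passed when adjusted over the list alone. The list had a median log2 fold change of -0.57 and a mean of 0.17, so median and mean differed in sign, and as a set it did not stand apart from other genes (camera adjusted p = 0.495). Its genes changed in either direction (fry adjusted p = 0.000204).

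Single genes of other kinds rose in Ross cardiac fat. SS2 (Entrez 395106), a gene of the somatostatin family, averaged 0.0900 ± 0.172 FPKM in abdominal and 31.4 ± 35.2 FPKM in cardiac fat, with a log2 fold change of 3.84 (adjusted p = 0.000121). The Wnt receptor FZD1 rose by 2.19, the differentiation inhibitor ID4 by 2.24, the matrix protein gene FBLN1 by 1.95 and the mesenchymal factor PRRX1 by 1.90 on the log2 scale, with adjusted p-values from 3.32e-08 to 0.00498. The extracellular matrix list as a set was not called (camera adjusted p = 0.495), with FBLN1 the 1 member of 5 that passed, also when adjusted over the list alone. IGFBP4, which binds insulin-like growth factors, rose from 69.5 ± 32.6 to 213 ± 67.6 FPKM (log2 fold change 1.69), the only 1 of 5 tested genes of the insulin and growth hormone axis that passed. RPL35 was the single ribosomal protein gene of 8 that passed, with a log2 fold change of 1.26 (adjusted p = 2.00e-05). The immunoglobulin chain gene IGJ had a log2 fold change of 2.33 (adjusted p = 0.0236), with values from 2.41 to 579 FPKM within Ross cardiac fat, and its call was lost without Ross abdominal library 1199 or Ross cardiac libraries 1207 or 1210.

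Some endothelial genes, an adrenergic receptor gene and 3 of 4 immediate early genes were lower in Ross cardiac fat. Of 5 tested endothelial genes, SOX18 and ERG, both transcription factors of vessel cells, fell, with log2 fold changes of -1.17 and -0.73, and 3 fell when adjusted over the list alone. The endothelium list was lower as a set (camera adjusted p = 0.0440), with adjusted p = 0.471 with an estimated correlation and 0.0750 after quantile normalization. The adrenergic receptor gene ADRA1B fell from 10.2 ± 3.16 to 1.997 ± 1.30 FPKM (log2 fold change -1.99, adjusted p = 1.36e-05). Of 4 immediate early genes, EGR1 (-1.64), SGK1 (-0.84) and PER2 (-0.80) fell, while CTGF, a matricellular growth factor gene, rose by 0.78 on the log2 scale. The chromatin protein gene HMGA1 had a log2 fold change of -1.78 and the differentiation-related gene IFRD1 of -1.69. PPARG, the master regulator of fat cell differentiation, fell from 62.6 ± 18.3 to 39.2 ± 18.9 FPKM (log2 fold change -0.79, adjusted p = 0.0262). FABP4 averaged 13951 ± 1475 and 16619.7 ± 7345 FPKM and was not called (log2 fold change 0.09, adjusted p = 0.863).

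In all, limma called 120 of 423 genes between the Ross depots, 77 higher and 43 lower in cardiac fat. After quantile normalization the calls split into 55 higher and 61 lower. The median log2 fold change of all genes moved from 0.10 to -0.01 with that step, and that of the trial comparison from -0.25 to 0.03, or -0.01 after upper quartile scaling. Within the trials, the log2 fold change of TBX20 was 3.68 in Fall 12 and 3.13 in Fall 13, and the corresponding pairs were 1.07 and 3.53 for TBX18, 1.14 and 2.76 for FBLN1, 0.39 and 3.41 for PRRX1, 5.70 and 1.99 for SS2, -1.38 and -2.95 for PITX1, and -2.11 and -1.18 for EGR1. Fewer genes passed within a trial, 35 in Fall 12 and 59 in Fall 13, with TBX18, FBLN1, PRRX1, PITX1, NKX3-2, SOX18, ERG, IGFBP4, PPARG and PER2 not called within Fall 12, and HMGA1, NKX3-2, ERG, SGK1, PPARG and PER2 not called within Fall 13. Without the libraries with a muscle signal, Ross cardiac 1208 and 1209 included, the count was 111, but the calls of PPARG (adjusted p = 0.0718), CTGF, CALD1 and CLOCK were lost. CTGF was not called within either trial, and PPARG, CALD1, CLOCK and BIRC5 were not called without the trial term.

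**Figure D2:**
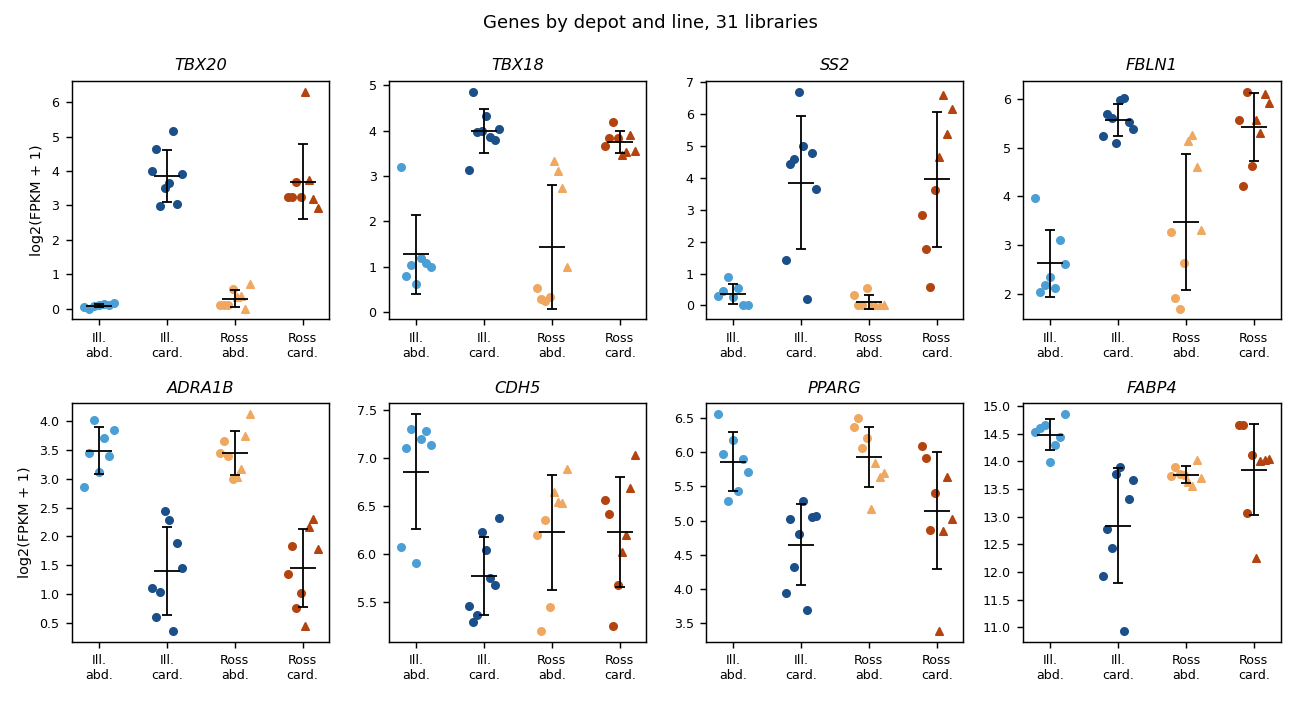
Expression of 8 genes as log2(FPKM + 1) in the 4 groups. Points are libraries, with triangles for Fall 12 and circles for Fall 13, and bars show the mean and SD. TBX20, TBX18, SS2 and FBLN1 lie higher in cardiac fat of both lines and ADRA1B lower, whereas FABP4 is lower in cardiac fat of the Illinois line, with a log2 fold change of -1.64.

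In the Illinois line, cardiac fat had more of TBX20, TBX18 and TBX5 and less of TBX2 (-1.08, adjusted p = 0.00867), FABP4, PPARG, CAV1 and 3 endothelial genes than abdominal fat, while TBX3 was not called (-0.77, adjusted p = 0.0784). TBX20 rose from 0.0646 ± 0.0391 (SD, n = 7) to 15.5 ± 9.52 FPKM (SD, n = 8; log2 fold change 3.77, SE 0.34, adjusted p = 3.06e-09), with 8 of 8 cardiac libraries above the abdominal median. TBX18 rose by 2.72, TBX5, a factor of the forelimb and heart, by 2.61, and PITX1 had a log2 fold change of -1.91. FABP4 fell from 23235 ± 4317 to 8868 ± 4979 FPKM (log2 fold change -1.64, adjusted p = 0.000941) and PPARG from 59.5 ± 18.7 to 25.8 ± 9.59 FPKM (log2 fold change -1.21, adjusted p = 0.00179). PPARG was the 1 of 4 tested adipogenic regulators that passed, and the list had a median log2 fold change of 0.31. Without the 4 libraries with a muscle signal the change of FABP4 was -1.17 (adjusted p = 0.000836), and its mean over both lines moved from -0.77 to -0.42 and was not called (adjusted p = 0.0522). FABP4 ranked first in every library, so quantile normalization gave it the same value in all and removed its call. CAV1, which builds the caveolae of fat and vessel cells, fell from 474 ± 54.1 to 169 ± 46.9 FPKM (log2 fold change -1.52, adjusted p = 1.76e-06), with 8 of 8 cardiac libraries below the abdominal median.

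Of 5 endothelial genes, 3 fell in Illinois cardiac fat, also when adjusted over the list alone. These were the junction genes CLDN5 (-1.86) and CDH5 (-1.08) and the growth factor receptor gene FLT1 (-0.82). The list was lower as a set (camera adjusted p = 0.0138; adjusted p = 0.515 with an estimated correlation). The extracellular matrix list was higher (camera adjusted p = 0.0413; adjusted p = 0.515 with an estimated correlation), but 1 of its 5 members passed, FBLN1, from 5.91 ± 4.11 to 47.6 ± 11.2 FPKM (log2 fold change 2.94), and 2 rose when adjusted over the list alone. Of the developmental regulators, 3 were higher and 2 lower of 9 (3 and 3 when adjusted over the list alone), with a median of -0.42, a mean of 0.44, a camera adjusted p of 0.805 and a fry adjusted p for either direction of 0.000175.

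Single genes of other kinds were called as well. ADRA1B (-2.08), the adenosine receptor gene ADORA1 (-1.74), the Wnt receptor gene FZD6 (-1.30) and the G-protein regulator RGS2 (-1.26) fell, as did OPTC, a small matrix proteoglycan gene (-1.98). SS2 (3.50), PRRX1 (2.18) and IL1RL1, a cytokine receptor gene (2.32), rose. In the insulin and growth hormone axis, IGFBP4 rose by 1.61, while FOXO1, a factor restrained by insulin, and SOCS2 fell, with log2 fold changes of -0.62 and -0.45. The call of SOCS2 (adjusted p = 0.0492) held in 16 of 49 alternatives. ALDH1A1, which makes retinoic acid, rose from 8.97 ± 4.83 to 36.5 ± 16.3 FPKM (log2 fold change 1.98, adjusted p = 0.00230), and of the clock genes ARNTL had a log2 fold change of -0.70, a call lost without the 4 libraries with a muscle signal. The muscle myosin gene MYH7B had a log2 fold change of 2.98 (adjusted p = 0.0282). It reached 163 and 53.0 FPKM in libraries 1112 and 1107, and its change was 1.82 (adjusted p = 0.0277) without the 4 libraries with a muscle signal.

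Limma called 79 genes between the Illinois depots, 31 higher and 48 lower in cardiac fat, and 52 higher and 42 lower after each library was scaled to the same upper quartile, which moved the median log2 fold change of all genes from -0.02 to 0.10. All Illinois libraries came from 1 trial, so no second trial was there to compare.

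Many depot differences were seen in both lines. Of the 77 genes higher in Ross cardiac fat and the 31 higher in Illinois cardiac fat, 23 were the same, where 5.64 would be shared by independent lists (Fisher's exact test, two-sided, p = 1.17e-12). Of the 43 and 48 lower genes, 15 were the same, against 4.88 (Fisher's exact test, two-sided, p = 1.16e-05). Both tests take genes as independent. The shared higher genes included TBX20, TBX18, TBX5, SS2, FBLN1, FZD1, ID4, PRRX1, IGFBP4, IL1RL1 and CHRNA3, an acetylcholine receptor gene of autonomic nerves. The shared lower genes included PITX1, ADRA1B, ADORA1, OPTC, PPARG and SGK1. QSOX1 and PARK7 were called in opposite directions in the lines. Averaged over lines, limma called 128 genes, 66 higher and 62 lower, which became 63 higher and 89 lower after quantile normalization, with the median log2 fold change of all genes moving from 0.05 to -0.06.

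The line comparison in abdominal fat asked how Ross birds differ from Illinois birds at the same trial level. The relative depths of the 2 groups did not overlap (1.15 to 1.58 in Illinois and 0.512 to 1.07 in Ross), nor did their library numbers. The line thus cannot be told apart from depth or from a library batch, if there was one. Library numbers also did not overlap between the depots of a line, between the lines in cardiac fat, or between the trials within a Ross group. A library batch cannot be told apart from those differences either. CDKN2A (Entrez 395077), a brake on cell division, was lower in Ross, at 14.0 ± 5.00 FPKM in Illinois (SD, n = 7) and 4.66 ± 3.15 in Ross (SD, n = 8; log2 fold change -1.53, SE 0.35, adjusted p = 0.00320), with 8 of 8 Ross libraries below the Illinois median. The chemokine gene CXCL12 averaged 35.1 ± 11.8 FPKM in Illinois and 3.93 ± 1.22 FPKM in the 4 Ross libraries of Fall 13 (log2 fold change -2.84 in Fall 13 libraries alone, adjusted p = 6.46e-06), but 54.3 ± 23.1 FPKM in the 4 of Fall 12. The fit of all libraries, with 1 trial effect for both depots, gave -2.19 (adjusted p = 0.000838). HMGA1 was higher in Ross, at 10.7 ± 5.92 against 44.9 ± 12.0 FPKM (log2 fold change 2.20, adjusted p = 0.00120), with 8 of 8 Ross libraries above the Illinois median.

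Other genes lower in Ross abdominal fat were the RNA-binding gene CELF1 (-2.43), FZD6 (-1.72), the cholesterol exporter ABCA1 (-1.59), the fibrillin gene FBN2 (-1.44) and the guidance receptor NRP2 (-1.42). Among the fixed lists, single members fell. These were CDH5 of 5 endothelial genes (-0.97), BUB1B of 4 cell cycle genes (-1.25), RPL35 of 8 ribosomal protein genes (-1.12), ARNTL of 6 clock genes (-1.03), ATP5A1 of 2 oxidative phosphorylation genes (-1.03), CTGF of 4 immediate early genes (-1.04) and the chaperone HSP90B1, the single tested folding gene (-1.37). Higher in Ross were ADD3, a gene of the membrane skeleton (1.40), the actin crosslinker ACTN1 (1.07), the kinase gene HIPK2 (1.02), SUFU, a brake on Hedgehog signalling (0.94), and BCL2L1, which protects cells from apoptosis (0.89). MRAS (0.83) and THYN1 (0.75) were also higher. Of lipid genes, ME1, which supplies reducing power for fatty acid synthesis (0.70, adjusted p = 0.0479), and PPARA, a regulator of fatty acid oxidation (0.96, adjusted p = 0.0303), were higher, while PPARG (0.46, adjusted p = 0.303) and FABP4 (-0.57, adjusted p = 0.314) were not called. No list of 5 or more genes passed, with camera adjusted p-values of 0.986 or higher.

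Limma called 63 genes, 17 higher and 46 lower in Ross, and 41 higher and 45 lower after quantile normalization. In Fall 13 libraries alone HIPK2, SUFU, MRAS, THYN1, ATP5A1 and BUB1B were not called, and the log2 fold change was -1.57 for CDKN2A, 1.79 for HMGA1, -1.87 for FZD6 and -1.51 for ABCA1. Without the trial term, 49 genes were called, 29 of them among the 63, and the calls of CXCL12, ABCA1, NRP2, CDH5, HSP90B1, CTGF, ME1 and THYN1 were lost. With only the abdominal libraries in the fit, MRAS, THYN1, ME1, PPARA and BUB1B were not called. EEF1A1, a translation factor gene with a log2 fold change of -5.63, ranged from 4.96 to 2093 FPKM within Ross abdominal fat and lost its call without the trial term (-3.36, adjusted p = 0.0978).

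**Figure D3:**
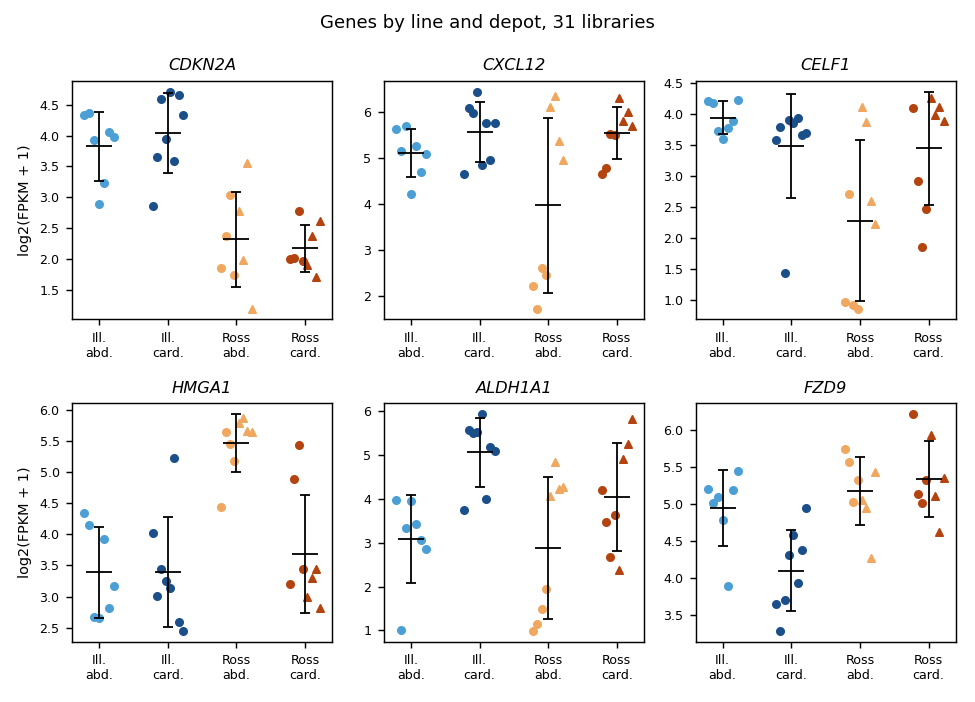
Expression of 6 genes as log2(FPKM + 1) in the 4 groups. Points are libraries, with triangles for Fall 12 and circles for Fall 13, and bars show the mean and SD. CDKN2A lies lower in both Ross groups, and CXCL12 is lower in Ross abdominal fat of Fall 13 than of Fall 12.

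CDKN2A was also lower in Ross cardiac fat, where it averaged 16.9 ± 7.05 FPKM in Illinois and 3.64 ± 1.29 in Ross (SD, n = 8 each; log2 fold change -1.89, SE 0.34, adjusted p = 0.00161), with 8 of 8 Ross libraries below the Illinois median. ALDH1A1 was lower in Ross, with a log2 fold change of -2.04 (adjusted p = 0.0125), and 2 of 3 retinoid genes fell when adjusted over the list alone. IFRD1 (-1.31), EGR1 (-1.26), the deacetylase HDAC4 (-0.95), the Wnt feedback gene AXIN2 (-0.89), the fat cell regulator EBF3 (-0.79) and the phosphatase DUSP6 (-0.63) were also lower. Higher in Ross were the Wnt receptors FZD9 (1.41) and FZD2 (0.80), the disulfide-forming enzyme QSOX1 (1.31), the vessel-associated gene PALD1 (1.06), the guidance cue SEMA3F (1.00), the sulfatase ARSH (0.90), PARK7, which protects from oxidative stress (0.77), and the sialyltransferase ST3GAL2 (0.74). PPARG (0.88, adjusted p = 0.0616) and FABP4 (1.16, adjusted p = 0.0529) were not called, and no list of 5 or more genes passed (camera adjusted p of 0.135 or higher; after quantile normalization the extracellular matrix list had an adjusted p of 0.0478, and adjusted p = 0.561 with an estimated correlation).

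Limma called 26 genes, 18 higher and 8 lower in Ross, with splits of 35 and 26 after quantile normalization and 17 and 40 after upper quartile scaling, where the median log2 fold change of all genes was -0.14. With only the 16 cardiac libraries in the fit, CDKN2A alone was called (-1.85, adjusted p = 0.0133), while 80 genes had an unadjusted p below 0.05. In Fall 13 libraries alone its log2 fold change was -1.85, and those of FZD9 and QSOX1 were 1.32 and 1.27. ALDH1A1, with -1.57 (adjusted p = 0.0514), EGR1, HDAC4, AXIN2, EBF3 and DUSP6 were not called there or without the trial term. SEMA3F and FZD2 were not called in Fall 13 alone, and IFRD1 (-0.60, adjusted p = 0.370), PALD1 and PARK7 were not called without the trial term.

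A test of the difference between the depot effects asked whether the lines differ in how cardiac fat departs from abdominal fat. FABP4 fell in cardiac fat of Illinois birds (-1.64) and had a change of 0.09 in Ross birds, a difference of 1.73 on the log2 scale (SE 0.48, adjusted p = 0.0285). CAV1 differed in the same sense, with depot effects of -1.52 in Illinois and -0.20 in Ross (difference 1.32, adjusted p = 0.00301), and so did the endothelial gene CDH5 (difference 1.09, adjusted p = 0.0431). PARK7 fell in Illinois cardiac fat (-0.42) and rose in Ross cardiac fat (0.90), a difference of 1.31 (adjusted p = 5.02e-05), and QSOX1 did likewise, with a difference of 1.40 (adjusted p = 0.00708). The differences were also positive for RPL35 (1.40), ATP5A1 (1.33), CELF1 (1.62) and the calcium-binding S100A6 (1.41).

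Genes whose depot effect was more negative in Ross included HMGA1 (-1.78), IFRD1 (-1.66) and IL15, a cytokine gene (-1.48, adjusted p = 0.0347). PPARG showed no called difference (0.42, adjusted p = 0.533). The deacetylase gene HDAC1 was listed at 0.001 in each of the 8 Ross cardiac libraries, whereas Ross abdominal libraries ranged from 7.11 to 14.0 FPKM, and both Illinois groups held libraries at 0.001 and others above 5 FPKM. SULT1B1, a sulfotransferase gene called between the Ross depots, was listed at 0.001 in each Ross cardiac library but also in 4 of 8 Ross abdominal, 6 of 7 Illinois abdominal and 4 of 8 Illinois cardiac libraries, and its call held in 22 of 50 alternatives.

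Limma called 46 genes, 36 with a more positive and 10 with a more negative depot effect in Ross, with splits of 23 and 12 after quantile normalization and 25 and 18 after upper quartile scaling, where the median difference of all genes moved from 0.10 to -0.00277. Depot effects of these genes had opposite signs in 35 of 46, but only 2 had a called depot effect in both lines. The depot effect was called in Ross only for 30, in Illinois only for 12 and in neither line for 2. Choosing genes for a large difference favours opposite signs. The count of called differences was 22 without the 4 libraries with a muscle signal, where FABP4 (1.49), CAV1 (1.36), PARK7 (1.14), QSOX1 (1.36) and RPL35 (1.31) were still called, 13 without the trial term and 6 in Fall 13 libraries alone. The calls of HMGA1, CDH5, CELF1, S100A6 and HDAC1 were lost in each of these 3 fits, those of IFRD1, IL15 and ATP5A1 without the trial term and in Fall 13 alone, that of QSOX1 in Fall 13 alone, and that of FABP4 in Fall 13 alone (1.98, adjusted p = 0.0687) and after quantile normalization. No gene list of 5 or more genes passed for this difference (camera adjusted p of 0.242 or higher).

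**Figure D4:**
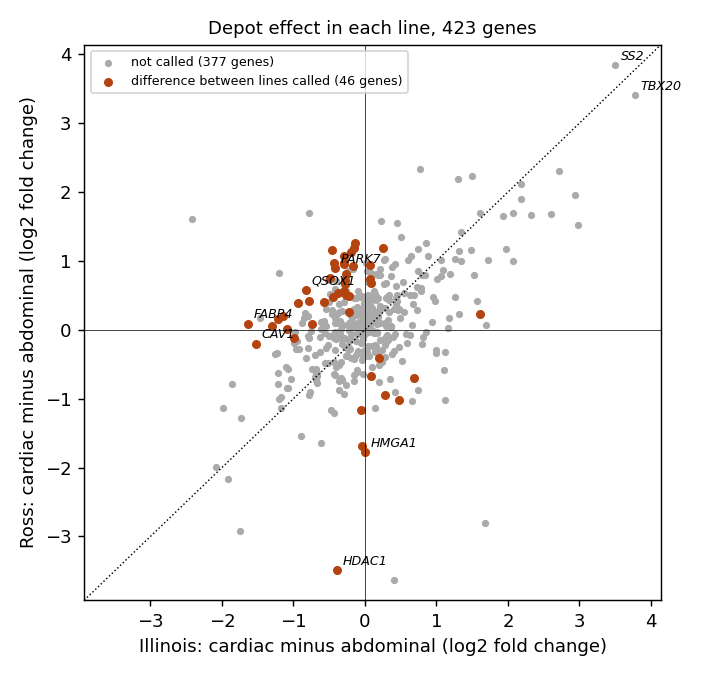
Log2 fold change between cardiac and abdominal fat in the Illinois line (horizontal) and the Ross line (vertical) for 423 genes, each point 1 gene. Coloured points are the 46 genes whose depot effects differ between lines at an adjusted p below 0.05, and the dotted line marks equal effects. TBX20 and SS2 lie near that line, and FABP4 and CAV1 lie to the left of it.

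The trials differed within Ross birds. CXCL12 was lower in Fall 13, from 54.3 ± 23.1 to 3.93 ± 1.22 FPKM in abdominal and from 61.2 ± 11.9 to 34.9 ± 11.1 FPKM in cardiac fat (SD, n = 4 each; log2 fold change -2.13, SE 0.39, adjusted p = 0.00123). Also lower were ABCA1 (-1.79), NRP2 (-1.88), ALDH1A1 (-2.03), the matrix glycoprotein gene THBS1 (-2.66) and the receptor gene BMPR2 (-2.10). ME1 (1.04), OPTC (1.34) and PPARG (0.77, a call lost without the 4 libraries with a muscle signal) were higher, and FABP4 was not called (0.30, adjusted p = 0.430). These genes were chosen for this comparison after their values were seen. Limma called 124 genes, 24 higher and 100 lower in Fall 13, with splits of 53 and 56 after quantile normalization and 45 and 62 after upper quartile scaling. Tested per depot, 111 genes were called in abdominal and 30 in cardiac fat, while the difference between depots was called for 6, namely CXCL12, CHRNA3, SS2, TBX18, PRRX1 and STK25. For PRRX1, the depot effect in Ross was larger in Fall 13 by 3.02 (adjusted p = 0.0446), and for CXCL12 by 2.59 (adjusted p = 0.0121). The line comparisons rest on this difference being the same in both depots and lines, since Illinois libraries came from Fall 13 only, and for CXCL12 it was not the same in both depots. Of the 63 line calls in abdominal fat 31 were also trial calls, where 18.5 would be expected if independent, and of the 26 in cardiac fat 14, where 7.62 would be expected. The line estimates and the trial estimate share Ross libraries, so they are not independent.

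**Figure D5:**
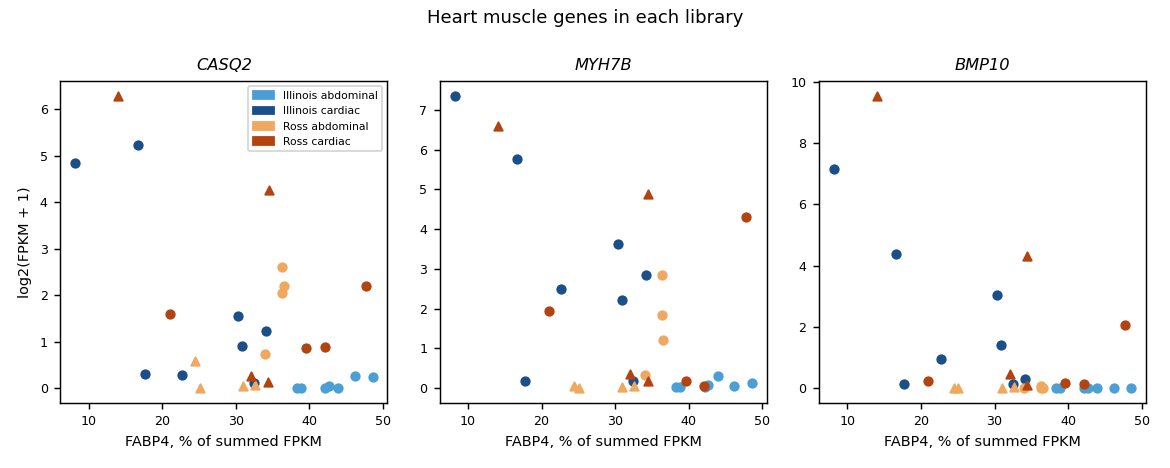
Expression of the heart muscle genes CASQ2, MYH7B and BMP10 as log2(FPKM + 1) against the share of FABP4 in the summed FPKM, with 1 point per library. Colours mark groups, triangles mark Fall 12 and circles Fall 13. CASQ2 exceeds 10 FPKM in 4 cardiac libraries, the highest at 77.2 FPKM.

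The lists with fewer than 5 tested genes gave few further calls. In Ross cardiac against abdominal fat, the contractile gene CALD1 fell (-0.62, adjusted p = 0.0338; -1.17 in Fall 12 and -0.07 in Fall 13), ATP5A1 rose (1.14), and the cell division gene BIRC5 rose (0.79, adjusted p = 0.0294). CHRNA3, the single tested nerve gene, rose in both lines, by 1.42 in Ross and 1.34 in Illinois, but by 2.72 in Ross birds of Fall 12 and 0.11 in those of Fall 13. Of 6 clock genes, CLOCK (-0.58) and PER2 fell between the Ross depots, and the direction of CLOCK was reversed in Fall 13 (0.03).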

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

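The tests of the heart muscle, fat cell share, counting noise, group switching and failed estimate explanations were chosen after the results were seen.

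In 24 of the 306 sets of named gene and group, the highest or lowest library lay apart from the rest by the Dixon ratio, the gap to the next library over the range of the group on the log2(FPKM + 1) scale. Chance alone gives about 1 in 20, or 15.3 sets. In Ross cardiac fat, library 1208 was the highest for TBX20 (0.760, 78.0 FPKM against 6.61 to 12.3 in the others) and TBX5 (0.551, 95.6 FPKM), and the lowest for PPARG (0.539, 9.46 FPKM). Library 1206 was the highest for PRRX1 (0.751) and IGFBP4 (0.641), and library 1211 for EBF3 (0.551). In Illinois cardiac fat, library 1107 was the lowest for AXIN2 (0.556), FLT1 (0.5677) and BUB1B (0.594), library 1109 the highest for IGJ (0.617) and the lowest for CELF1 (0.856, 1.72 FPKM), and library 1112 the highest for ATP5A1 (0.645). In Illinois abdominal fat, library 1092 was the highest for TBX18 (0.780, 8.21 FPKM against 0.536 to 1.28), and library 1094 the highest for MYH7B (0.621) and ATP5A1 (0.620) and the lowest for CLOCK (0.643). Library 1096 of that group was the highest for SULT1B1 (1, 37.2 FPKM against 0.001 in the others) and the lowest for QSOX1 (0.607) and ARSH (0.585). Library 1093 was the lowest for ALDH1A1 (0.619) and PPARA (0.727, listed at 0.001), library 1097 for FZD9 (0.574) and library 1098 for EEF1A1 (0.854, 32.3 FPKM). In Ross abdominal fat, library 1198 was the lowest for CAV1 (0.602, 147 FPKM).

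The depot effect differed between lines, by limma's interaction test, for 18 named genes. The difference, Ross minus Illinois on the log2 scale, was -3.10 for HDAC1, which is listed at 0.001 in each Ross cardiac library, so that the value rests on the pseudocount and ranged from -6.05 to -1.40 over the alternatives. It was -1.78 for HMGA1, -1.66 for IFRD1, -1.48 for IL15 and -1.38 for ADD3. It was positive at 1.73 for FABP4, 1.62 for CELF1, 1.41 for S100A6, 1.40 for QSOX1, 1.40 for RPL35, 1.36 for FZD6, 1.35 for NRP2, 1.34 for PALD1, 1.33 for FBN2, 1.33 for ATP5A1, 1.32 for CAV1, 1.31 for PARK7 and 1.09 for CDH5.

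For the 23 genes higher in cardiac fat of both lines, heart muscle carried into the tissue was one explanation weighed, since CASQ2, MYH7B and BMP10 were high in 4 cardiac libraries. Without those libraries all 23 genes were still called for the mean depot effect. That test pools both lines, so it keeps calls more readily than the tests per line that chose the genes. The median log2 fold change of the 23 genes moved from 1.65 to 1.54, which argues against muscle in those libraries as the whole cause. It may account for part of single genes of the set, since the change of TBX5 moved from 2.15 to 1.44. MYH7B, a muscle gene outside the set, moved from 2.25 to 0.98 and lost its call for the mean effect (limma, adjusted p = 0.0663). It was still called between the Illinois depots, so the cut on CASQ2 may not remove all muscle. A lower share of fat cells, with the other cell types kept in proportion, would raise markers of all of these. The 5 tested endothelial genes had a median of -0.61 and 5 of 5 were called lower for the mean over lines. In Ross alone 2 of 5 were called lower, and CDH5 changed by 0.005 (limma, adjusted p = 0.988). The list was already known to be lower when it was chosen, so it is no independent test. None of the 5 was called higher for the mean, so these genes did not rise as that simple form would have them. A lower share of fat cells together with fewer vessel cells stays open. So does another difference in cell makeup, or in gene activity between the depots.

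A second pattern is the 63 genes listed at 0.001 in some libraries and at 5 FPKM or more in others of the same group. The checks below cover the 54 of them that were among the tested genes. Counting noise at low depth is argued against, since in 84 of 85 pairs of gene and group the depth and the level of the other libraries would give 10 or more fragments (median 686), although choosing genes that reach 5 FPKM favours such a count. Expression switched between groups cannot be told apart by the test run, in which the libraries at the floor followed the groups for 1 of 54 genes, HDAC1 (Fisher's exact test, adjusted p = 0.0137), because the genes were chosen for differing within a group and 26 were at the floor in 1 library of 31. Estimates that failed for single libraries are a candidate explanation for part of the genes, since 10 of them reached 100 FPKM in another library of the same group. Of these, GPX4, LSP1 and NBL1 were at the floor in 1 library of 31. RPL39 was at the floor in 24 of 31, so its estimate would have had to fail in many libraries. That was not tested and stays open. HDAC1 stays open, because a failed estimate in each Ross cardiac library and a true absence of transcript look alike in these values.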

How the results depend on the processing

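The alternatives on muscle libraries, CASQ2, the floor and the header number were chosen after seeing the data, the others in advance. Of 6447 values of 135 named gene results under alternatives, 5827 kept their side of the threshold, 4 of these being uncalled values that changed sign, 599 lost and 19 gained a call and 2 reversed. Only 37 of the 135 results changed in no alternative. Calls that held in fewer alternatives than not were those of CLOCK (16 of 51) and SULT1B1 (22 of 50) between the Ross depots, SOCS2 (16 of 49) between the Illinois depots, MRAS (21 of 47) and ME1 (22 of 47) for the line in abdominal fat, EBF3 (18 of 47) for the line in cardiac fat, and FBN2 (14 of 46) and CDH5 (21 of 47) for the difference of depot effects. CLOCK between the Ross depots moved from -0.58 to 0.0293 with Fall 13 libraries only and to 0.0293 with Fall 13 Ross libraries only. Counts of calls moved as follows, and the cause was not tested except where fewer libraries or a stricter null hypothesis give it. Against a log2 change of 0.5, calls were 16 for the Ross depots, 22 for the Illinois depots, 7 for the line in abdominal fat, 0 in cardiac fat (limma, 19 at an unadjusted p below 0.05), 1 for the difference of depot effects, 27 for the mean depot effect and 20 for the trial. The line in cardiac fat (26) rose to 39 with a pseudocount of 0.1, 61 with quantile normalization, 57 with upper quartile scaling, 48 with array weights, 48 with CASQ2 as a covariate and 43 without genes that alternate with the floor, and fell to 1 with its own libraries only. The line in abdominal fat (63) rose to 99 with upper quartile scaling. The difference of depot effects (46) gave 13 without the trial term, 6 in Fall 13 only and 22 without the 4 muscle libraries. The Ross depots (120) gave 65 in Fall 13 libraries only, 60 by the exact rank test, and 35 and 59 in Ross libraries of Fall 12 and Fall 13. Gene list tests passed 3 of 30 with camera and 0 with an estimated correlation, against 4 with fry, 2 with fry in either direction and 4 after quantile normalization.

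Leaving out 1 library in turn gave 104 to 127 calls for the Ross depots, 66 to 92 for the Illinois depots, 41 to 68 for the line in abdominal fat, 18 to 43 for the line in cardiac fat, 24 to 50 for the difference of depot effects, 114 to 138 for the mean depot effect and 108 to 150 for the trial. Counts moved by over 1.5 times for the line in abdominal fat without Ross abdominal 1198 (41), for the line in cardiac fat without Illinois cardiac 1107 (43), and for the difference of depot effects without Illinois abdominal 1094 (24) or 1093 (30) or Ross abdominal 1201 (24) or 1199 (30). Over these fits, 286 of 4185 named values lost and 8 gained a call, and 0 reversed.

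An abdominal and a cardiac library share the second number of the column headers in 15 pairs. Each pair lies within the same line and the same trial, but no source says what the number stands for. The correlation of their deviations ran from -0.232 to 0.365 (median 0.105), above 0.1 in 8 pairs, and 13 of 30 libraries correlated best with their own number, where 5.88 would by chance (permutation p = 0.0157, chosen after the result was seen). This is a hint from the data that some pairs share a source. The model fixed in advance held no such block, so its p-values treat the libraries as independent. The correlations of single pairs cannot settle this. If the number names the bird, the depot comparisons are paired. With the number as a replicate block, calls were 133, 90, 60, 24, 55 and 150 for the Ross depots, the Illinois depots, the line in abdominal and in cardiac fat, the difference and the mean, and with a fixed block 122, 83, 38 and 140 for the Ross and Illinois depots, the difference and the mean. The fixed block kept 109 of 120, 72 of 79, 31 of 46 and 122 of 128 calls of the model without a block, in the same order. The count-based alternative was not run because the values are FPKM. Absolute depth is unknown. In a typical gene of the 103 with low values, 1 FPKM rested on about 33.3 fragments at median depth. The precision of low values in other genes stays open.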

Other observations

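The tests of the trial explanations were chosen after the results were seen, whereas the counts over other splits of the libraries were fixed in advance.

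Beyond the genes described above, further single genes were called between the depots in both lines. Those given here were chosen after their values were seen and were not tested as a set. Higher in cardiac fat were FBN3, a fibrillin gene (1.66 in Ross and 1.94 in Illinois, log2), CHRDL1, an antagonist of bone morphogenetic proteins (1.70 and 2.08), the guidance cue SLIT3 (1.18 and 0.74), the carboxypeptidase CPZ (1.07 and 0.89), the cartilage factor SOX9 (0.78 and 1.07) and AXIN2 (0.74 and 1.01). Lower were the basement membrane collagen COL18A1 (-1.14 and -1.18), the integrin ITGB1 (-0.63 and -1.22), the cytokine receptor LIFR (-0.85 and -1.07), the mineralocorticoid receptor NR3C2 (-0.48 and -0.51) and DBI, which binds acyl-CoA (-0.97 and -1.17).

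Genes of heart muscle rose together in the same libraries. MYH7B stood at 53.0 FPKM in Illinois cardiac library 1107, 163 in 1112, 94.9 in Ross cardiac library 1208 and 28.3 in 1209. BMP10, a growth factor of the heart, stood at 19.8, 141, 747 and 19.1 FPKM in the same order. Illinois cardiac libraries 1108 and 1109 had FABP4 shares of 22.7% and 17.7% without such levels.

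The trial difference in Ross was a further pattern, with 124 calls of which 100 were lower in Fall 13. The overall scale of the values is argued against as the whole cause, since 80 of the calls kept their call and direction after quantile normalization. It cannot be told apart for the excess of lower calls, which fell from 76 to 3 (53 higher and 56 lower) while the median of all genes moved from -0.25 to 0.03, because this normalization centres the libraries. A bias with transcript length cannot be told apart, because sizes were known for 15 of the 124 genes, and long coding genes differed from short ones by -0.43 on the log2 scale (medians of -0.39 over 24 and 0.04 over 38 genes, permutation p = 0.0619 over genes, which are not independent). A difference between the birds or seasons of the trials stays open, as untested.

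Other splits of the same libraries bear on whether chance can be excluded, with 100 splits per comparison, the real one included. In 1 of 100, the real one, the count of calls was reached for the Ross depots (120, highest of the others 67), the Illinois depots (79 and 5), the line in abdominal fat (63 and 7), the line in cardiac fat (26 and 25), the difference of depot effects (46 and 2), the mean depot effect (128 and 1) and the trial (124 and 2). Counts as high were thus rare among these splits. For the difference of depot effects, the splits exchange depot labels within each line, which also breaks up the depot effects themselves. They do not test whether the depot effects are equal in the lines, so chance is not settled for that difference. The line splits exchange libraries of different trials, which differed in Ross, so they do not test the line alone. The splits cannot tell the line apart from a library batch, and do not settle whether libraries are paired. For the line in cardiac fat the margin was 1 gene. Leaving out 1 library gave 18 to 43 calls there, and a fit of its own libraries only gave 1. Chance is therefore not excluded for the line in cardiac fat. For gene list tests in the depot comparisons, 6 of 100 splits gave 3 or more, the highest 4, so chance is not excluded.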
